A study of Mus musculus with 12 samples.

How the data were processed

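RNA was measured in cultures of SIM-A9, a mouse microglial cell line, in its wild-type form (WT) and in the H14 line, which the labels give as a knockout of the kinase MOK (KO). Each line received medium alone or lipopolysaccharide (LPS) at 1 µg/mL for 5 h. The labels give 3 biological replicates in each of the 4 groups, 12 libraries in all, and do not describe how the replicate cultures were separated, so the p-values measure the spread between these samples. Libraries were stranded total RNA libraries depleted of ribosomal RNA, per the labels' protocols. One KO line was sequenced, so loss of MOK and any other difference between the lines cannot be separated in these data.

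The deposited table holds raw read counts per Ensembl gene, as whole numbers, for the 12 libraries. Reads were processed with FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.9a and featureCounts on GRCm39, and DESeq2 1.32.0 was used, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The table lists 55416 gene identifiers, of which 52083 matched a symbol in the reference annotation (GENCODE on GRCm38). Identifiers without a symbol held 6.49% of the counts and stayed in the library totals and the tests. Because the builds differ, the reference served only for gene names, gene classes and transcript sequences, and no coordinates are given.

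Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (count minimum 10), which left 26420 genes, 16152 of them protein-coding and 4633 processed pseudogenes. Libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit, robust) with 4 group means was fitted over all 12 libraries. The biological coefficient of variation was 0.235. The 5 comparisons were LPS against medium in WT, LPS against medium in KO, KO against WT in medium, KO against WT under LPS, and the interaction, which is the LPS effect in KO minus the LPS effect in WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Log2 fold changes are given with the standard error (SE) of the model, and counts per M counts of the scaled library (CPM) as mean ± SD with n = 3. A mean LPS effect over both lines of at least 1 on the log2 scale, with adjusted p under 0.05, defined LPS-induced genes, and at most -1 defined LPS-repressed genes. This choice uses another combination of the group means than the interaction.

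Gene lists, 36 in number and holding 800 entries, were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists within a comparison), and 4 of the entries were not found among the gene symbols. Camera with an estimated correlation and fry served as alternatives. The level of a list in a library is the mean log2 CPM (prior count 2) of its genes, and its line difference under LPS was tested with a two-sided exact permutation test. For 3 libraries against 3 the smallest p such a test can give is 0.1. The interaction of a list's level was tested with limma on the 36 levels per library, with line, treatment and their interaction in the model and Benjamini-Hochberg adjustment over the lists, a test chosen after the results were seen.

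The comparisons, the lists and the rule for the genes named were chosen before the data were examined. The rule took 15 genes fixed by name in every comparison. It added the 6 genes with the largest positive and the 6 with the largest negative fold change per comparison, among called genes with a mean log2 CPM of at least 2, a regular gene symbol and, outside the interaction, no overlap between the libraries of the groups. From each list it took the 3 called members with the largest change at that mean and the most abundant member, and among LPS-responsive genes the 6 largest called interactions in each direction at that mean with a regular symbol. Some genes that this rule names are not reported here.

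Sequence sharing between genes was measured as the percent of a gene's 31-mers that also occur in transcripts of another gene. Alternatives set before the data were examined were RLE scaling, library size alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, robust estimation off, the replicate number as a block, only the groups compared, the 50 most abundant genes left out, each library left out, and other definitions of LPS-responsive genes. Alternatives added after seeing the data were protein-coding genes only, protein-coding genes with under 5% shared 31-mers, the log2 share of counts in processed pseudogenes as a covariate, and only libraries with under 8% of counts in processed pseudogenes.

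The fit was tested on simulated counts with known changes. For KO against WT under LPS (25982 genes), 51 of 100 genes changed 2-fold and 85 of 100 changed 4-fold were recovered, and 7 of 143 calls were false. For the interaction (25892 genes), 37 of 100 and 68 of 100 were recovered, and 3 of 108 calls were false. Each gene was simulated independently, without a shift shared by many genes of a library, such as that of the pseudogene share in the real libraries. These shares of false calls therefore do not measure the error in the real libraries. Total counts were 39.7 M to 72.9 M per library. Intervals on counts are 95% Clopper-Pearson intervals and cover counting error only, since the reads carry no molecular identifiers.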

Results

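Gene expression was measured by stranded total RNA sequencing in SIM-A9 cells, a mouse microglial line, and in an H14 line labelled as a knockout of MOK, a serine/threonine kinase related to the MAP kinases. Cells were given medium alone or LPS, the bacterial cell wall component that activates Toll-like receptor 4, at 1 µg/mL for 5 h, with 3 libraries in each of the 4 groups. Total counts in replicates 1, 2 and 3 were 44.0 M, 41.1 M and 57.1 M for WT in medium and 68.1 M, 43.5 M and 72.9 M for WT under LPS. In the KO line they were 46.9 M, 39.7 M and 45.6 M in medium and 50.1 M, 57.6 M and 46.7 M under LPS. Replicates of a group differed by a chi-square per degree of freedom between 22.8 and 185.8 for pairs of libraries, a spread set against counting noise alone. The highest values were those of KO LPS replicate 2 against replicates 1 and 3 (185.8 and 103.3) and of WT medium replicate 2 against replicate 3 (157.6). KO LPS replicate 2 also held 10.4% of its counts in identifiers without a symbol, against 4.88% to 8.18% in the other 11 libraries.

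Mok was detected in all 12 libraries and its mean was lower in the KO line. Its counts in replicates 1, 2 and 3 were 158, 163 and 206 in WT and 115, 117 and 95 in KO in medium, and 164, 87 and 158 in WT and 78, 84 and 56 in KO under LPS. It was at 3.35 ± 0.16 CPM (SD, n = 3) in WT and 2.25 ± 0.33 CPM in KO in medium, and at 2.50 ± 0.33 CPM in WT and 1.52 ± 0.19 CPM in KO under LPS. KO cells had a log2 fold change of -0.72 ± 0.19 (SE) under LPS (edgeR adjusted p = 0.0177) and of -0.58 ± 0.19 in medium (adjusted p = 0.0501), where it missed the threshold. Gene-level counts do not show whether the remaining transcripts carry an edit, so they check the labels only in part. The call under LPS was lost without WT LPS replicate 1 (adjusted p = 0.0785), WT LPS replicate 3 (0.0515) or KO LPS replicate 3 (0.0753).

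The LPS response of the parental line was the first comparison. In WT cells, LPS raised cytokine, chemokine and interferon-stimulated genes strongly. Cxcl2, a neutrophil-attracting chemokine, rose 2550-fold and Cxcl10, a T cell-attracting chemokine induced by interferon, rose 1520-fold, from 0.78 ± 0.13 to 1198 ± 198 CPM (SD, n = 3). Tnf rose from 6.56 ± 0.35 to 1837 ± 190 CPM, a log2 fold change of 8.13 ± 0.17 (SE; adjusted p = 1.77e-10). Il6 (log2 fold change 9.73 ± 0.52), Il1b (7.22 ± 0.27), Ccl5 (8.64 ± 0.75) and Nos2, the inducible nitric oxide synthase (5.30 ± 0.19), rose as well. Of the 61 interferon-stimulated genes measured, 60 rose and none fell, with a median log2 fold change of 4.09 (camera adjusted p = 3.13e-141), among them Ifit1, the antiviral enzyme Rsad2 and Cmpk2 with log2 fold changes of 8.96, 8.87 and 8.78. All 31 NF-kB targets and feedback regulators rose (median 2.60, camera adjusted p = 4.55e-114), among them Traf1 (5.57 ± 0.13), the co-stimulatory receptor Cd40 (5.19 ± 0.14) and Nfkbiz (5.08 ± 0.12). Of 33 inflammatory cytokines and chemokines, 30 rose and 1 fell (median 4.65, camera adjusted p = 2.14e-90). Adjusted over the list alone, the counts were 61, 31 and 31 genes higher in these 3 lists. Nitric oxide and reactive oxygen genes rose in 14 of 15 cases, including Ptgs2, which makes prostaglandins (7.22 ± 0.21), and Acod1, which makes itaconate (6.78 ± 0.29). Immediate early genes and MAPK feedback regulators (22 of 30 higher), p53 targets (11 of 19 higher, with Fas at 4.18) and adhesion and matrix genes (15 of 28 higher, with the urokinase receptor Plaur at 2.72) also passed camera, and these calls held with an estimated correlation (adjusted p = 0.0355, 0.0196 and 0.0315).

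Downregulated genes in WT included Bmf, a pro-apoptotic BH3-only protein, which fell from 16.2 ± 2.8 to 1.58 ± 0.38 CPM (log2 fold change -3.35 ± 0.29, adjusted p = 5.44e-06). Slc26a11 (-3.14), the G protein regulator Rgs2 (-2.99), the sphingosine phosphate receptor S1pr1 (-2.87), Kbtbd11 (-2.79) and Gpr157 (-2.73) followed. Homeostatic microglia markers were not called as a list (9 of 26 lower, 5 higher, camera adjusted p = 0.124, and 0.0459 without WT medium replicate 2). Of 30 genes of G1/S and DNA replication, 15 fell and 1 rose, with E2f1 at -1.28 and Ccne1 at -1.10 (camera adjusted p = 0.000247, and adjusted p = 0.655 with an estimated correlation). The Ccne1 call was lost without WT medium replicate 2 (adjusted p = 0.0621) or WT LPS replicate 1, 2 or 3 (0.0856, 0.103 and 0.0713). Some of these genes share sequence with others, namely Cxcl2 (7.59% of 31-mers), Ifit1 (10.8%), Kbtbd11 (24.8%) and Gpr157 (5.59%), so their counts are less certain. All 18 genes of MHC class I presentation rose (median 1.23), including the peptide transporter Tap1 at 2.91 and B2m at 0.77, with a camera adjusted p of 3e-16 and an adjusted p of 0.1 with an estimated correlation. In all, 4303 of 26420 genes rose and 4297 fell, with 1476 and 2473 of them by at least 2-fold. Among protein-coding genes 3729 rose and 2198 fell, and 1295 of the genes that fell were processed pseudogenes. When protein-coding genes were filtered and scaled on their own, 3231 rose and 3213 fell, so the excess of rising coding genes depends on the processing. With the pseudogene share as a covariate 2313 fell, and libraries with a low share gave 2113 higher and 2131 lower. Scaling by library size alone moved the median of all genes from -0.07 to -0.40 and gave 2104 higher and 9985 lower. Without WT LPS replicate 1, 2 or 3 the lower count was 2094, 2513 and 2288.

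**Figure D1:**
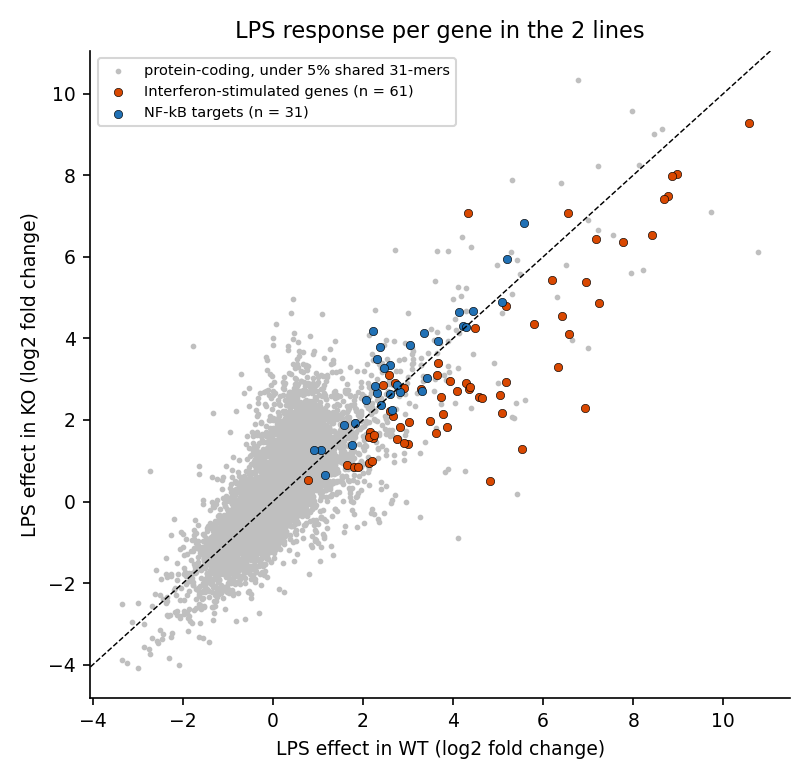
Log2 fold change under LPS in KO cells (vertical axis) against that in WT cells (horizontal axis), 1 point per gene, with the dashed line marking equal effects. Grey points are protein-coding genes with under 5% shared 31-mers, blue points 31 NF-kB targets and orange points 61 interferon-stimulated genes, whose median effect was 4.09 in WT and 2.75 in KO.

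The KO line also responded to LPS with induction of the same families. Cxcl2 rose 3190-fold, Acod1 1290-fold and Ccl2, a monocyte-attracting chemokine, 763-fold, from 2.09 ± 0.15 to 1597 ± 332 CPM (SD, n = 3). Tnf rose from 4.15 ± 0.31 to 1256 ± 185 CPM (log2 fold change 8.24 ± 0.17, adjusted p = 1.25e-10), Nos2 by a log2 fold change of 7.89 ± 0.21 and Il1b by 8.23 ± 0.30. All 31 NF-kB targets rose (median 3.04, camera adjusted p = 9.56e-106) and 29 of 33 cytokines and chemokines rose with none lower (median 4.96, camera adjusted p = 2.62e-62). Of the interferon-stimulated genes, 57 of 61 rose and none fell, with a median of 2.75 (camera adjusted p = 5.01e-61, and adjusted p = 0.058 with an estimated correlation). Adjusted over the list alone, 58 interferon-stimulated genes, 31 NF-kB targets and 29 cytokines and chemokines were higher. Cxcl10 rose 620-fold, Rsad2 254-fold and Irf7, an interferon regulatory factor, 8.62-fold. Among genes of cholesterol synthesis and uptake, 16 of 24 rose and 1 fell, with Hsd17b7 at 1.42 ± 0.10 and Msmo1 at 1.06 ± 0.07 (camera adjusted p = 4.64e-07, and adjusted p = 0.228 with an estimated correlation). NRF2 targets rose in 14 of 20 cases, including Srxn1 (2.35) and Txnrd1 (1.74), with a camera adjusted p of 7.95e-07 and an adjusted p of 0.205 with an estimated correlation.

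Genes that fell in the KO line under LPS included S1pr1 (log2 fold change -3.56 ± 0.33), the haematopoietic transcription factor Lyl1 (-3.48 ± 0.13) and the endosomal receptor Tlr13 (-3.33 ± 0.22). Acta1 (-4.09 ± 0.86, adjusted p = 0.00367) and Aldoart1 (-2.97 ± 0.66) also passed the test. Both lost their call with the share of counts in processed pseudogenes as a covariate, at 0.10 and 0.27 (adjusted p = 0.954 and 0.814). Their changed sign is uncertain, because treatment overlaps with that share in the KO line. That share was 12.8% to 14.3% in KO in medium, 6.64% to 7.35% in KO under LPS, 6.57% to 13.1% in WT in medium and 6.28% to 7.05% in WT under LPS. Processed pseudogenes made up 3233 of the 7070 genes that fell in KO. The counts of changed genes were 6679 higher and 7070 lower, or 5362 and 2754 among protein-coding genes. Protein-coding genes filtered and scaled on their own gave 4075 higher and 4192 lower, so their excess of higher genes did not hold there. Over all genes the counts with library size alone were 4182 and 10422, and with the pseudogene share as a covariate 1342 and 659. Fold changes of both lines correlated across genes (Pearson r = 0.828 over 26420 genes, which are not independent replicates, and 0.779 over protein-coding genes), with 3442 genes higher and 3287 lower in both. Among protein-coding genes 3066 were higher and 1549 lower in both, so in the main fit the shared lower genes were in large part of other classes. Independent lists would share 1088 and 1150 (1238 and 374.8 among protein-coding genes), the comparisons have no library in common, and 68 genes were called in opposite directions.

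**Figure D2:**
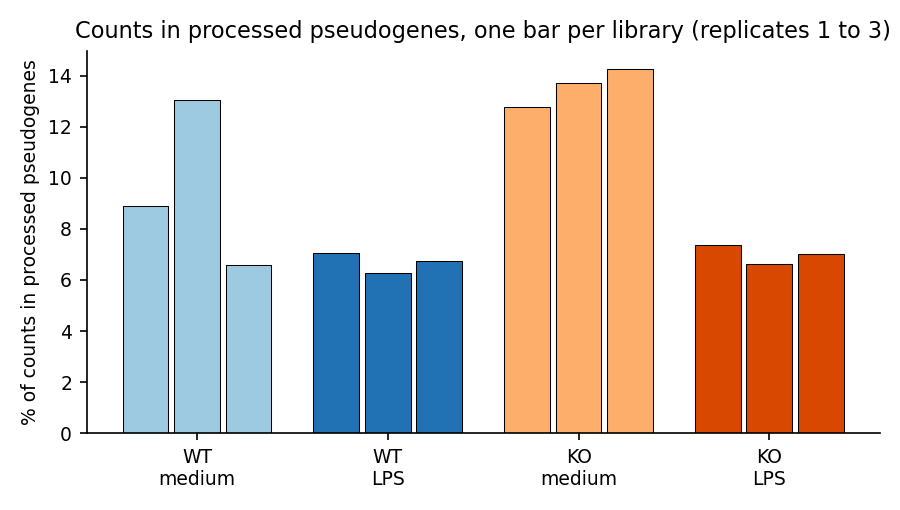
Percent of each library's counts in processed pseudogenes, 1 bar per library in the order of replicates 1 to 3 within each group. The bars run from 12.8% to 14.3% for KO in medium and from 6.57% to 13.1% for WT in medium, and no LPS library exceeds 7.35%.

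Differences between the lines without LPS were next. In medium, KO cells had far lower levels of a set of genes, several with roles in myeloid cells. Slc7a2, a cationic amino acid transporter, was at 40.9 ± 2.3 CPM (SD, n = 3) in WT and 0.24 ± 0.06 CPM in KO, 165-fold lower (log2 fold change -7.36 ± 0.19, adjusted p = 2.87e-09). The netrin receptor Neo1 (-7.18 ± 0.19), the mitochondrial calcium uniporter subunit Mcub (-6.99 ± 0.19), the complement C5a receptor C5ar1 (-6.52 ± 0.29), the GM-CSF receptor subunit Csf2ra (-6.24 ± 0.19) and the cytokine Il1a (-6.21 ± 0.29) were lower too. Higher in KO were the immunoglobulin heavy chain gene Ighm (12.5 ± 4.9 against 169 ± 32 CPM, 3.76 ± 0.29), the focal adhesion protein Tns1 (3.72 ± 0.34), the prostaglandin D synthase Ptgds (3.24 ± 0.23), the kinase Camk2a (2.88 ± 0.16), Nsmaf (2.74 ± 0.16) and Pianp (2.59 ± 0.27). Slc7a2 and Il1a share 8.78% and 10% of 31-mers with other genes.

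Inflammatory genes were lower in unstimulated KO cells as well. Of 15 nitric oxide and reactive oxygen genes, 11 were lower and 1 higher, with Nos2 8.38-fold lower, the NADPH oxidase subunit Cybb at -3.98 ± 0.55 and Acod1 at -3.66 ± 0.26 (camera adjusted p = 1.22e-18, and adjusted p = 0.12 with an estimated correlation). Of the cytokines and chemokines, 13 of 33 were lower and none higher, including Il1b (-2.26 ± 0.29) and its antagonist Il1rn (-4.19 ± 0.22), with a camera adjusted p of 1e-07 and an adjusted p of 0.245 with an estimated correlation. Interferon-stimulated genes had 31 of 61 lower and 2 higher (median -0.93), with Irf7 at -2.05 ± 0.26, Samd9l at -3.10 ± 0.37 and Oas2 at -2.70 ± 0.18. Their camera adjusted p was 3.82e-09, and adjusted p = 0.613 with an estimated correlation. Adjusted over the list alone, 32 were lower and 4 higher. Cholesterol synthesis and uptake genes were lower in 17 of 24 cases and higher in none (median -0.48), with Stard4, a sterol transport protein, at -2.22 ± 0.12 and lanosterol synthase, Lss, at -0.81 ± 0.08 (camera adjusted p = 2.02e-09, and adjusted p = 0.372 with an estimated correlation). Lysosome and autophagy genes were lower in 14 of 24 cases, with Npc2 at -0.73, and 1 was higher (camera adjusted p = 2.39e-05, and adjusted p = 0.584 with an estimated correlation). Npc2 lost its call without WT medium replicate 1 (adjusted p = 0.0562) or KO medium replicate 2 (0.0507). Isg15 did not pass the test in medium (-0.11 ± 0.38, adjusted p = 0.855).

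The total was 1818 genes higher and 3256 lower in KO in medium, or 1239 and 2785 among protein-coding genes, and 362 processed pseudogenes were higher and 48 lower. With the pseudogene share as a covariate the counts were 558 and 1784. The higher count was 977, 6110 and 1005 without WT medium replicates 1, 2 and 3, and 1050 and 907 without KO medium replicates 1 and 3, while the lower count was 5155 without WT medium replicate 2.

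The lines were then compared under LPS. Under LPS, KO cells reached much lower levels of interferon-stimulated genes than WT cells, and lower levels of several cytokines. Cxcl10 was at 1198 ± 198 CPM (SD, n = 3) in WT and 256 ± 50 CPM in KO, 4.69-fold lower (log2 fold change -2.23 ± 0.18, adjusted p = 4.66e-06), and Rsad2 at 4095 ± 460 and 785 ± 442 CPM (-2.38 ± 0.44, adjusted p = 0.00299). Of the 61 interferon-stimulated genes, 57 were lower and none higher (median -2.00), among them Samd9l (-4.67 ± 0.35), Cmpk2 (-3.15 ± 0.43) and Irf7 (-2.58 ± 0.26). Their camera adjusted p was 1.38e-61, and adjusted p = 0.0868 with an estimated correlation. Adjusted over the list alone, 59 were lower and none higher. The level of the list differed by -2.12 (exact permutation p = 0.1, the smallest that 3 libraries against 3 can give). Isg15 did not pass the test over all genes (-0.85 ± 0.32, adjusted p = 0.0933). The lowest level of the list among KO LPS libraries was in replicate 2, at a mean log2 CPM of 3.94 against 4.89 and 4.68 in replicates 1 and 3 and 6.63 ± 0.14 in WT. Without that replicate the median was -1.70.

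**Figure D3:**
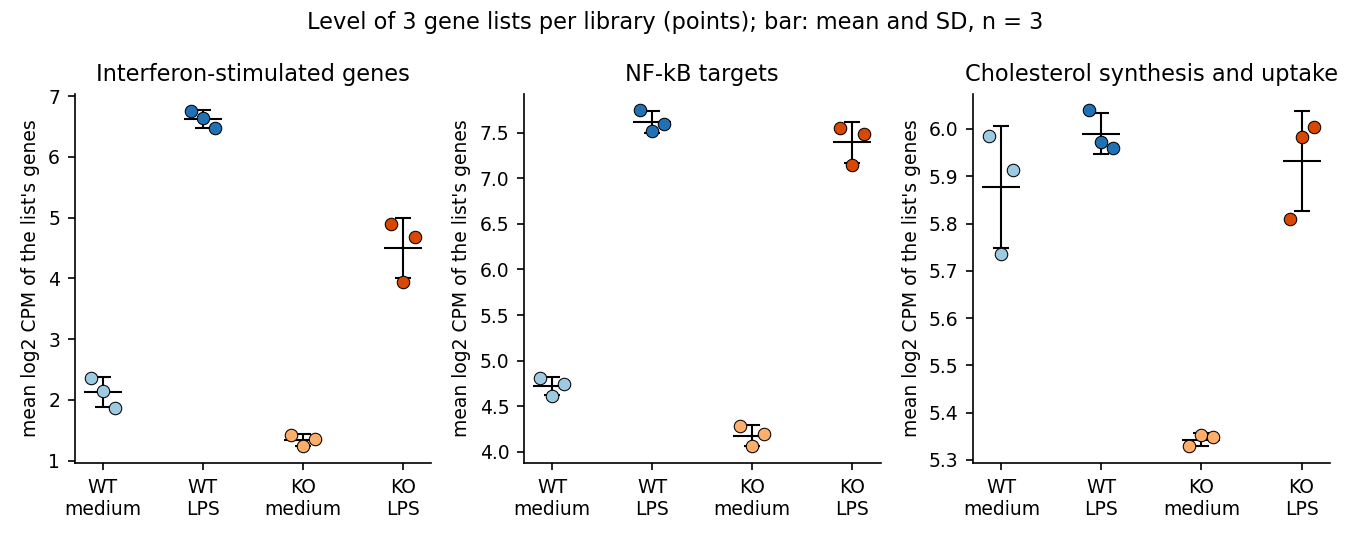
Mean log2 CPM of the genes of 3 lists in each library (points), with the group mean and SD (bars, n = 3). Interferon-stimulated genes reached 6.63 ± 0.14 in WT and 4.50 ± 0.50 in KO under LPS, and cholesterol genes stood at 5.88 ± 0.13 in WT and 5.34 ± 0.01 in KO in medium.

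Cytokines and chemokines under LPS were lower in KO in 18 of 33 cases and higher in 4. Il6 was 3.68-fold lower (-1.88 ± 0.32, adjusted p = 0.00177), Ccl4, a chemokine for monocytes, 8.78-fold lower (-3.14 ± 0.25), Il1b 2.36-fold lower and Tnf 1.46-fold lower (-0.55 ± 0.12, adjusted p = 0.00663). Camera gave an adjusted p of 5.18e-12 for the list, and adjusted p = 0.0868 with an estimated correlation. Ccl5 did not pass the test (-0.63 ± 0.52, adjusted p = 0.495). Ifnb1, the interferon beta gene, was at 2.61 ± 1.09 CPM in WT and 0.83 ± 0.37 CPM in KO (-1.67 ± 0.46, adjusted p = 0.0239). Its 429 counts under LPS against 1 in medium gave a count ratio of 420 in WT (95% Clopper-Pearson interval 75 to 16600), and its 114 against 2 gave 58.3 in KO (15.8 to 487). The Ifnb1 call was lost without WT LPS replicate 1 (adjusted p = 0.11), KO LPS replicate 2 (0.0813) or KO LPS replicate 3 (0.0549). Nos2 was at -0.49 ± 0.16 (adjusted p = 0.0491) and lost its call without any WT LPS replicate, KO medium replicate 3 or KO LPS replicates 2 or 3, with adjusted p between 0.055 and 0.142.

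Some receptor and uptake genes were lower in KO under LPS too. Tlr4 was 2.22-fold below WT (-1.15 ± 0.12, adjusted p = 3.76e-05). It was lower in medium already, at 65.0, 54.0 and 54.2 CPM in the WT replicates and 43.2, 32.4 and 36.5 CPM in the KO replicates. Of 29 Toll-like receptor pathway genes, 12 were lower under LPS and 2 higher, with Tlr13 at -3.19 ± 0.22 (camera adjusted p = 3.61e-07, and adjusted p = 0.362 with an estimated correlation). Phagocytosis and Fc receptor genes had 9 of 23 lower and 1 higher, with Fcgr1 at -1.59 and the phagocytic receptor Axl higher at 1.64 (camera adjusted p = 0.000117, and adjusted p = 0.554 with an estimated correlation). Lysosome and autophagy genes had 17 of 24 lower and 1 higher (camera adjusted p = 5.51e-06, and adjusted p = 0.554 with an estimated correlation). Among the 11 genes of sterol efflux, 6 were lower, including the cholesterol exporter Abca1 (-1.35) and Apoe (-1.15), with a camera adjusted p of 0.000866 and an adjusted p of 0.0868 with an estimated correlation. Apoe lost its call without WT LPS replicate 1 (adjusted p = 0.0514). NF-kB targets were not called as a list (3 of 31 higher, 9 lower, camera adjusted p = 0.0681), and neither were cholesterol synthesis and uptake genes (4 of 24 higher, 3 lower, camera adjusted p = 0.818). The NF-kB list did pass without WT LPS replicate 2 (adjusted p = 0.0146), KO medium replicates 1 or 3 (0.0427 and 0.0493) or KO LPS replicates 1 or 3 (0.0048 and 0.0225), and the p was 0.653 without KO LPS replicate 2. Slc7a2 (-7.75 ± 0.18), Neo1 (-7.35 ± 0.19), Igsf6 (-6.57 ± 0.27), C5ar1 (-6.53 ± 0.26), Csf2ra (-6.37 ± 0.18) and Mcub (-6.21 ± 0.18) were lowest among called genes with a mean log2 CPM of at least 2, a regular symbol and no overlap between the groups. Highest among these was Cx3cl1, the ligand of the microglial receptor Cx3cr1, at 19.5 ± 4.2 CPM in WT and 352 ± 92 CPM in KO (18.1-fold), followed by Ptgds (3.95), Ighm (3.82), Ip6k3 (3.50), Tns1 (3.46) and Atp2b4 (3.35).

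The counts under LPS were 2080 genes higher and 3351 lower in KO, and 2922 and 2936 with library size alone. Without WT LPS replicate 1 the higher count was 1382. The line differences in medium and under LPS, which share no library, had 877 genes higher and 2234 lower in both, where independent lists would share 143.1 and 413, and 32 were called in opposite directions. Their fold changes correlated with r = 0.541 across 26420 genes, which are not independent replicates.

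**Figure D4:**
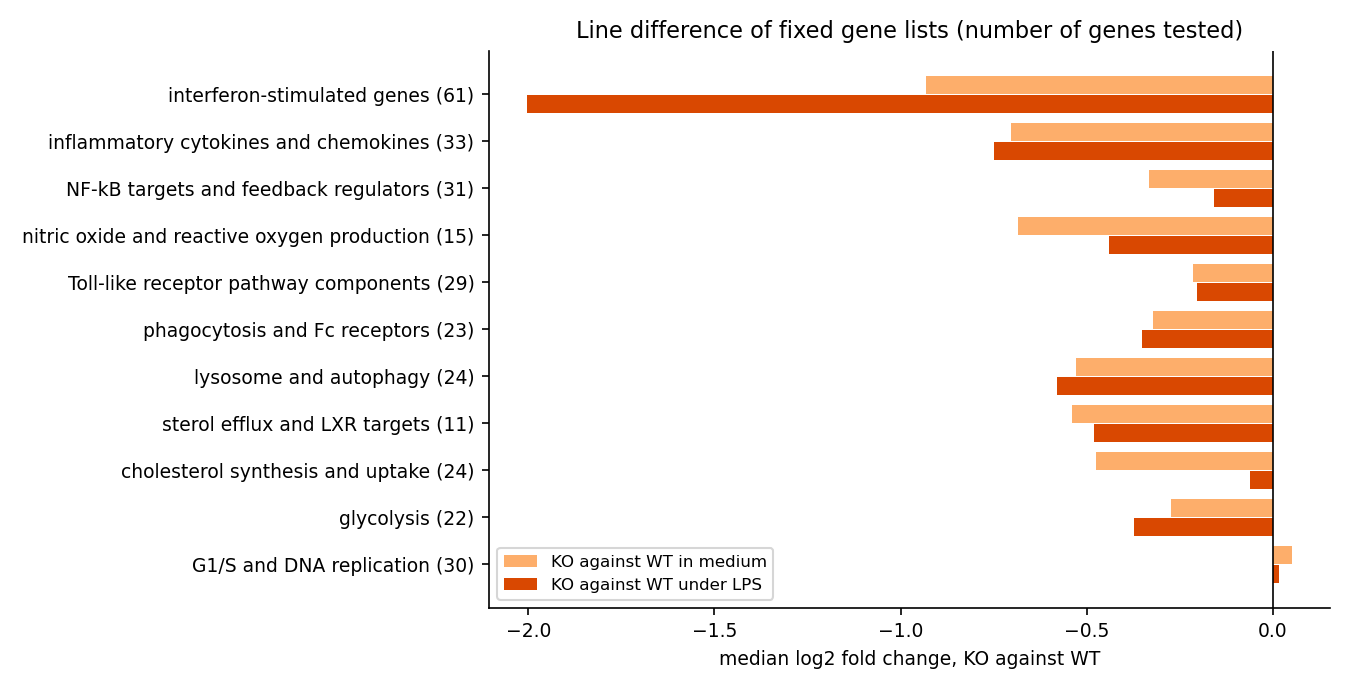
Median log2 fold change of KO against WT for 11 gene lists, in medium (light bars) and under LPS (dark bars), with the number of genes tested in brackets. The longest bar is that of interferon-stimulated genes under LPS, at -2.00, and cholesterol synthesis and uptake stood at -0.48 in medium and -0.06 under LPS, where its median was 0.01 with library size alone.

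Whether the LPS response itself differed between the lines was tested by the interaction. Acod1 and Nos2, which started lower in KO, were induced more strongly there: Acod1 went from 3.62 ± 1.23 to 4669 ± 1050 CPM in KO and from 45.8 ± 5.7 to 5013 ± 385 CPM in WT (SD, n = 3), an interaction of 3.55 ± 0.34 (SE; adjusted p = 0.000567). Nos2 had an interaction of 2.58 ± 0.23 (adjusted p = 0.000419). Its libraries lay at 6.43 to 7.76 CPM in KO and 53.3 to 65.1 CPM in WT in medium. Under LPS they lay at 1272 to 1962 CPM in KO and 2157 to 2522 CPM in WT. Both genes kept a lower mean in KO under LPS, so the stronger induction is relative to the level in medium. Treml4 (2.56 ± 0.25), the protease Adam8 (2.34 ± 0.26) and Stx11 (2.28 ± 0.33) followed. The transcriptional repressor Bcl6 fell in WT from 32.0 ± 2.2 to 10.2 ± 2.1 CPM and rose in KO from 28.7 ± 2.3 to 52.5 ± 5.5 CPM (2.52 ± 0.20, adjusted p = 0.000166). A lower LPS effect in KO was seen for Slfn4 (-3.44 ± 0.55), Themis2, a signalling adaptor (-2.19 ± 0.16, adjusted p = 0.000113), Herc6 (-2.04 ± 0.33), Rnf213 (-1.96 ± 0.25), the ISG15 protease Usp18 (-1.94 ± 0.32) and Ralgds (-1.92 ± 0.17). Interferon-stimulated genes had a median interaction of -1.21, with 18 of 61 lower and 1 higher (Rtp4, whose call was lost without any of 8 libraries, adjusted p up to 0.0867), or 38 lower and 1 higher adjusted over the list alone. Camera gave an adjusted p of 8.85e-34, and adjusted p = 0.506 with an estimated correlation. A limma test on the level of the list per library gave an interaction of -1.34 ± 0.29 (adjusted p = 0.0237). Without a library the interaction was -1.53 to -1.06 (limma adjusted p 0.00506 to 0.0683), and for the cholesterol list described next 0.42 to 0.55 (0.0121 to 0.0823). Exchanging libraries between the lines within each treatment gave unadjusted permutation p = 0.175 and 0.075 for these lists. Adjusted over the lists, the permutation p was 0.945 for both, but the line difference enters that test and holds its p up. Cholesterol synthesis and uptake genes had 6 of 24 with a higher LPS effect in KO and none lower, including Msmo1 (0.77 ± 0.10) and Hsd17b7 (0.79 ± 0.14), or 16 and none adjusted over the list alone. The camera adjusted p of the cholesterol list was 3.53e-13, and adjusted p = 0.506 with an estimated correlation. A limma test on its level gave 0.48 ± 0.11 (adjusted p = 0.024). Hsd17b7 lost its call without WT LPS replicate 2 (adjusted p = 0.0619) or replicate 3 (0.0559), and Usp18 with the pseudogene share as a covariate (0.0774). Slfn4, Herc6, Rnf213 and Rtp4 share 20.9%, 13.8%, 6.92% and 12.5% of 31-mers with other genes. NF-kB targets had 3 of 31 higher and none lower, with Traf1 at 1.26 ± 0.16 (camera adjusted p = 9.1e-05, and adjusted p = 0.953 with an estimated correlation). Tnf (0.11 ± 0.18, adjusted p = 0.794), Il6 (-2.62 ± 0.83, adjusted p = 0.189), Cxcl10 (-1.30 ± 0.33, adjusted p = 0.0873) and Ifnb1 (-2.54 ± 1.94, adjusted p = 0.587) did not pass.

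The interaction called 183 genes higher and 240 lower, or 360 and 236 with library size alone. Leaving out any library except KO medium replicate 2 moved the higher count by over 1.5 times, from 69 without WT LPS replicate 1 to 1606 without WT medium replicate 2, and the lower count ranged from 116 without KO medium replicate 3 to 2391 without WT medium replicate 2. Of 2639 LPS-induced genes, 120 had a lower and 69 a higher LPS effect in KO, and of 4364 LPS-repressed genes 15 and 6. Without WT medium replicate 2 the counts were 189 and 622 among induced genes and 1097 and 24 among repressed genes. Among induced genes, the lower count was 56 to 76 without WT medium replicate 1, WT LPS replicates 1 or 2, KO medium replicates 1 or 3 or KO LPS replicate 3. The higher count was 36 to 43 without WT medium replicate 1, any WT LPS replicate, KO medium replicate 3 or KO LPS replicates 1 or 3, and 152 without KO LPS replicate 2. Among repressed genes, the lower count was 4 to 8 without WT medium replicate 1, any WT LPS replicate, KO medium replicates 1 or 3 or KO LPS replicates 1 or 3, and the higher count was 3 without WT LPS replicate 1 or 2. The median interaction was 0.66 among induced and -0.74 among repressed genes, or 0.55 and -0.36 among the protein-coding ones. Among induced genes it was -0.22 when induced genes were chosen in WT alone, a choice that shares the WT libraries with the interaction. Among 1744 protein-coding induced genes, 94 were lower and 66 higher. Only 983 of the 4364 repressed genes were protein-coding, with 14 lower and 6 higher, so most of the repressed class was of other gene classes.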

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

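The tests of explanations, their bounds (for the interaction of a list, 2 SE from 0 in every setting) and the splits of the samples here were chosen after the results were seen, except the count of splits among protein-coding genes with few shared 31-mers. Results are given here because the LPS effect differed between the lines by a test of the difference itself. The interaction called 183 genes with a higher and 240 with a lower LPS effect in KO. Median interactions of the lists called by camera were -1.21 for interferon-stimulated genes, 0.27 for NF-kB targets, 0.037 for nitric oxide and reactive oxygen genes (mean 0.66), -0.17 for MHC class I presentation, 0.45 for cholesterol synthesis and uptake and 0.20 for NRF2 targets. None of these 6 calls held with an estimated correlation (adjusted p between 0.506 and 0.953). The MHC class I call was also lost without WT medium replicate 2, KO medium replicate 1 or KO LPS replicate 2 (0.362, 0.124 and 0.136), and the NRF2 call without WT LPS replicate 2 (0.166). Among LPS-responsive genes called for the interaction, with a regular symbol and a mean log2 CPM of at least 2, the largest interactions were those of Acod1 (3.55), Rtp4 (2.73), Nos2 (2.58), Treml4 (2.56), Adam8 (2.34) and Stx11 (2.28), and on the other side Ifi203 (-2.50), Ifit2 (-2.46), Herc6 (-2.05), Rnf213 (-1.96), Usp18 (-1.94) and Ralgds (-1.92). Rtp4 lost its call without any of 8 libraries, Ifit2 without any of 9 and Ifi203 without any of 5, with adjusted p up to 0.0867, 0.114 and 0.0753. All 3 kept their calls without WT medium replicate 2 or KO LPS replicate 1 or 2.

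For the interaction, 5 of 100 splits of the libraries between the lines gave as many calls as the real 423, and the highest other split gave 7656. Among protein-coding genes with few shared 31-mers, 9 of 100 splits gave as many calls as the real 471, with 4816 in the highest other. All of these other splits exchanged either all or none of the LPS libraries and so put the difference between the lines into the interaction, which points to the structure of the samples. Excluding chance asked for a share under 0.05, a bound set beforehand only for the genes with few shared 31-mers. Both shares missed it and so lay on the side of chance. The point about exchanged LPS libraries was not part of that bound. These counts therefore do not decide whether chance can be excluded. For the other comparisons, 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real and highest other counts were 8600 and 0 for LPS in WT, 13749 and 0 for LPS in KO, 5074 and 1200 for KO against WT in medium, and 5431 and 0 for KO against WT under LPS. The split with 1200 calls grouped WT medium replicates 1 and 3 with KO medium replicate 1, the 3 medium libraries with the lowest shares of counts in processed pseudogenes.

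The share of counts in processed pseudogenes differed between libraries, and within untreated WT alone its range was 81.1% of the range over all 12 libraries, so treatment and line of the cells were not its whole cause. Genomic DNA was argued against, because unconfirmed transcripts differed between WT medium replicates 2 and 3 by a median log2 of -0.12 and pseudogenes with no shared 31-mer by -0.23. Reads shared between pseudogenes and their parent genes are a candidate explanation, since pseudogenes with 5 to 50% shared 31-mers differed by a median of 2.23. The shift did not rise steadily with sharing, at 1.09 for pseudogenes with some but under 5% shared and 1.10 for those with over 50%. Parent genes moved the other way, with Gapdh at 351 CPM in replicate 2 and 1339 CPM in replicate 3. What made reads shift between the copies, and whether the KO line adds to it, stays open.

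Interferon-stimulated genes were lower in KO than in WT under LPS. Reads shared with other genes were argued against, because the 32 members among protein-coding genes with under 5% shared 31-mers had a median of -2.08. The median interaction of NF-kB targets was 0.27, above the bound of 0, so this list did not show a weaker LPS response in KO. Among LPS-induced genes, 26.7% had an interaction below 0 and the median was 0.66 (28.5% and 0.55 among protein-coding ones). Most of them therefore did not show a weaker response in KO. Of those called, however, 120 were lower and 69 higher. The median was -0.22 when induced genes were chosen in WT alone, a choice that shares the WT libraries with the interaction. Other lists went both ways in limma on their levels, so a weaker response in general was not decided. Nitric oxide and reactive oxygen genes had 0.69 ± 0.19 (adjusted p = 0.0425) and NF-kB targets 0.32 ± 0.16 (0.364). The nitric oxide list, whose median interaction was 0.037, lost its call without any of 8 libraries (limma adjusted p up to 0.121). It also lost it with the pseudogene share as a covariate (0.162). Cytokines and chemokines had -0.41 ± 0.16 (0.195) and Toll-like receptor pathway genes -0.27 ± 0.11 (0.208). Limma on the level of the list argued against a line difference that is the same in medium (interaction -1.34 ± 0.29, adjusted p = 0.0237). The adjusted p was 0.0657, 0.0683 and 0.0591 without WT medium replicate 3, WT LPS replicate 2 and KO medium replicate 3, where the interaction was -1.21 ± 0.30, -1.33 ± 0.33 and -1.33 ± 0.32, and 0.162 with the pseudogene share as a covariate (-1.16 ± 0.33). Loss of MOK and any other difference of the single KO line stay open as untested.

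Cholesterol synthesis and uptake genes were lower in KO than in WT in medium and not under LPS. Shared reads were argued against by the 18 members with under 5% shared 31-mers, 13 of which were lower, with a median of -0.41. Limma on the level of the list argued against a line difference of the same size under LPS (interaction 0.48 ± 0.11, adjusted p = 0.024). The adjusted p was 0.073 and 0.0823 without WT medium replicates 1 and 3, 0.0683 and 0.0784 without WT LPS replicates 2 and 3, 0.0591 without KO medium replicate 3 and 0.0742 without KO LPS replicate 3, where the interaction was 0.42 to 0.48, and 0.162 with the pseudogene share as a covariate (0.38 ± 0.13). A biological cause in the KO line was not tested.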

How the results depend on the processing

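The alternatives restricted to protein-coding genes, with the pseudogene share as a covariate or restricted to libraries with a low share were chosen after seeing the data. Where no cause is named below, the cause was not tested. RLE scaling changed no list call in 180 list tests, library size alone changed 10 (5 gained, 5 lost), and an estimated correlation ended 63. Only a called list can lose its call, so the 63 are to be set against the lists called and not against all 180. Of the named genes called in each comparison, 85 of 102 (LPS in WT), 77 of 101 (LPS in KO), 66 of 96 (KO against WT in medium), 81 of 97 (under LPS) and 22 of 41 (interaction) kept their call under every alternative.

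With an estimated correlation, interferon-stimulated genes had adjusted p = 0.058 for LPS in KO, 0.613 in medium, 0.0868 under LPS and 0.506 for the interaction, where fry gave 0.064, and cytokines and chemokines 0.245 in medium and 0.0868 under LPS. DESeq2 called 442 genes higher and 415 lower for the interaction, with 192 lower and 189 higher among induced and 29 lower and 15 higher among repressed genes. Library size alone gave 2104 higher and 9985 lower for LPS in WT, 4182 higher for LPS in KO, 360 higher for the interaction and 18 higher among repressed genes. RLE gave 8 lower among repressed genes. The stricter filter gave 289 higher for the interaction, and only the groups compared 802 higher in medium.

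Protein-coding genes only, filtered and scaled on their own, gave 3231 higher and 3213 lower for LPS in WT and 4075 higher and 4192 lower for LPS in KO. They gave 385 lower for the interaction and 30 lower among repressed genes. About as many coding genes were tested there (16162) as in the main fit (16152), so the number of genes does not account for the change. Protein-coding genes with few shared 31-mers gave 2145 and 2152 for LPS in WT, 2839 and 2908 for LPS in KO, and 71 lower among induced genes. Only low-share libraries, which leave 1 WT medium library that is assumed to vary like the other groups, gave 2113 and 2131 for LPS in WT. The pseudogene share as a covariate, which overlaps with treatment in the KO line, gave 2313 lower for LPS in WT, 1342 and 659 for LPS in KO, 558 and 1784 in medium, 73 and 125 for the interaction, 62 lower and 41 higher among induced and 9 lower among repressed genes. It turned the sign for LPS in KO of Acta1 (0.10), Aldoart1 (0.27), Gapdh (-0.17) and Rps2 (-0.051). None of these values passed the test (adjusted p between 0.814 and 0.984), so their signs are uncertain.

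Induced and repressed genes chosen in WT alone had 43 higher among induced, and 5 lower and 22 higher among repressed genes, and the median interaction of induced genes turned to -0.22. A limit of 2 on the log2 scale, with fewer genes, gave 56 lower and 30 higher among induced, and 4 lower and 0 higher among repressed genes.

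The replicate numbers were not used to pair the samples in the main fit, and the correlations do not settle whether they pair. Same-numbered libraries correlated between -0.366 and 0.391 (12 of 18 pairs over 0), and 6 of 12 libraries correlated best with their own number. With the replicate block, 311 genes were higher and 350 lower for the interaction, and 114 were higher among induced genes. The block also gave 2417 higher and 3769 lower in KO in medium, and 2542 and 3872 under LPS.

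Leaving out each library gave ranges of 2094 to 6337 (LPS in WT, lower), 907 to 6110 and 2477 to 5155 (medium, higher and lower), 1382 to 2288 (under LPS, higher), 69 to 1606 and 116 to 2391 (interaction). Among induced genes they were 56 to 189 lower and 36 to 622 higher, and among repressed genes 4 to 1097 lower and 3 to 24 higher. The upper ends for medium and the interaction were reached without WT medium replicate 2, the WT medium library with the highest pseudogene share. Depth limits low genes such as Ifnb1, with 1 and 2 counts in medium.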

Other observations

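Some further gene groups had members that were lower in KO, although no list call given here between the lines held with an estimated correlation. Glycolysis genes were lower in KO in medium (6 of 22, none higher) and under LPS (8 of 22, none higher), with the hexokinase Hk3 at -2.14 ± 0.10 (SE) and -1.97 ± 0.09, and camera adjusted p of 2.39e-05 and 1.65e-05 (0.584 and 0.554 with an estimated correlation). Genes of the integrated stress response had 11 of 29 lower and 3 higher in medium, with Chac1 at -2.82 and Trib3 at -2.12 (camera adjusted p = 0.0193, and adjusted p = 0.584 with an estimated correlation). Inflammasome genes had 6 of 16 lower and 1 higher in medium and 8 lower and 2 higher under LPS, with Nlrc4 at -2.08 ± 0.13 and -2.22 ± 0.13 (camera adjusted p = 0.0117 and 0.000799, and 0.584 and 0.362 with an estimated correlation). The kinase Cdk9, which releases paused RNA polymerase, was lower in KO in medium (-0.81 ± 0.06, adjusted p = 3.8e-06) and under LPS (-0.75 ± 0.06, adjusted p = 4.63e-06), while its list of bromodomain and elongation genes was not called (camera adjusted p = 0.26 and 0.566).

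Markers of disease-associated microglia had 9 of 25 lower and 2 higher in KO in medium, with Igf1 at -2.07 ± 0.41 and Axl at 2.06 ± 0.34 (camera adjusted p = 0.000732, and adjusted p = 0.627 with an estimated correlation). Mitosis genes had 10 of 30 lower in medium, with Bub1 at -0.80 and Aurka at -0.88 (camera adjusted p = 0.0161, and adjusted p = 0.812 with an estimated correlation), while genes of G1/S and DNA replication were not called in medium or under LPS (camera adjusted p = 0.92 and 0.811). Marker lists of astrocytes, neurons, oligodendrocytes, fibroblasts and lymphoid cells were not called between the lines (camera adjusted p between 0.217 and 0.976 in medium and between 0.389 and 0.824 under LPS).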
